A study of Arabidopsis thaliana with 48 samples.

How the data were processed

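The series measured mRNA by sequencing in whole Arabidopsis thaliana Col-0 seedlings, grown for 7 days in liquid medium. Seedlings of a wild-type line expressing the calcium reporter aequorin (WT) and of the mutant card1-2 (card1) received 5 µM of the quinone 2,6-dimethoxy-1,4-benzoquinone (DMBQ) or the same volume of its solvent, DMSO. Samples were taken at 0, 0.5, 1 and 6 h, so that 2 genotypes, 2 agents and 4 times gave 16 groups of 3 libraries. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. CARD1, the gene of the mutant, is AT5G49760 (also named HPCA1) and encodes a leucine-rich repeat receptor kinase. Per the labels, RNA was extracted with a Qiagen RNeasy kit, libraries were made with a KAPA mRNA HyperPrep kit, and sequencing was on a NextSeq500.

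The values used are raw counts of reads per gene that the authors deposited, 1 column per library. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq 0.6.1 and the TAIR10 genome were used. The annotation version, read trimming, strand setting and counting mode are not given in the sources used here, so counts of overlapping, antisense and near-identical genes are uncertain. The table held 33602 genes and 5 entries naming no gene, which were left out of library sizes and tests. Of all reads entered in the table, those entries took 1.28 to 2.08% (no feature), 0.655 to 0.735% (ambiguous), 2.64 to 7.25% (not aligned) and 6.53 to 13.3% (not unique) per library. Reads that map to several places were thus not credited to a gene, which lowers the counts of close paralogs. Symbols, transcript lengths and coordinates came from the TAIR10.1 annotation, in which 32835 of the gene identifiers (97.7%) had an entry. Genes with no symbol are given by identifier.

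Depth was 4764682 to 14492051 gene counts per library (median 8490000). The 48 replicate pairs had Spearman correlations of 0.979 to 0.995 across genes, and each differed by more than sampling noise (chi-square per degree of freedom 2.13 to 16.4), so no library was a copy of another in its own group.

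Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 over the 16 groups, which left 19839 genes, 107 of them from the organelles. TMM factors (0.933 to 1.088) scaled the libraries, 1 robust quasi-likelihood model with a mean per group was fitted to all 48 libraries, and 19 contrasts were tested with edgeR's quasi-likelihood test. P-values were Benjamini-Hochberg adjusted over all genes tested within a contrast and called at 0.05. The contrasts were DMBQ against DMSO at each time in each genotype, the difference of the 2 genotypes' responses at each time, joint tests over 0.5, 1 and 6 h, card1 against WT in DMSO as a mean of the 4 times, and each later time against 0 h in DMSO as a mean of both genotypes. Levels are given as library-scaled counts (CPM) with SD, fold changes as log2 values with the model's SE. No interval or error given covers differences between batches of seedlings.

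Gene lists numbered 23, written from textbook knowledge: glutathione S-transferases; xenobiotic conjugation and oxidation; quinone, enone and carbonyl reductases; WRKY factors; early stress ERF, CBF and ZAT factors; calcium signalling; pattern-triggered immunity; salicylic acid; jasmonic acid; ethylene. They also held redox and antioxidant enzymes, mitochondrial retrograde response, heat shock, xyloglucan endotransglucosylases, phenylpropanoid and lignin synthesis, tryptophan and camalexin synthesis, LRR VIII-1 receptor kinases, abscisic acid, auxin, the circadian clock and iron homeostasis. Photosynthesis and root markers followed the shares of shoot and root. Of 453 members written, 5 were dropped because the annotation gives their identifier another symbol, 405 were tested and 43 did not pass the filter on counts. Each list was tested in each contrast with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, adjusted over the lists of the contrast. A p "with an estimated correlation" is the same test with the correlation estimated from the list's own genes. A response score gave, per library, the mean log2 CPM of genes called in WT at another time, minus the mean of the same genotype and time in DMSO, compared by exact two-sided permutation tests (3 against 3 libraries, smallest possible p 0.1).

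The samples' groups, the tests, the lists, the alternatives named next and the rule for naming genes were set before the data were examined. By that rule CARD1 is always given. For WT after 0 h, the 10 largest rises and 10 largest falls are eligible among called genes with a mean log2 CPM of at least 1 and all 3 DMBQ libraries on the same side of all 3 DMSO libraries. Other contrasts take 5 of each, without the rule on sides for response differences and means of contrasts, and each list takes the 4 members with the smallest adjusted p. The alternatives were DESeq2 1.42.0, RLE scaling factors, no filter, a filter at mean log2 CPM of 1, only the compared groups' libraries, a minimum absolute log2 fold change of 1, a replicate block, each library left out in turn, and for lists an estimated correlation and fry (limma). For the score, genes with an absolute log2 fold change of at least 1 were an alternative.

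Further alternatives were added after the data were seen: a per-library correction for transcript length and GC content (a spline with 4 degrees of freedom, entered as offsets), the same with a replicate block, card1 DMSO 0 h replicates 1 and 2 left out, organelle genes left out, the genotype mean over 0.5, 1 and 6 h, and scores over genes called in card1. The labels give every group replicates 1 to 3. Deviations from the group means of same-numbered DMBQ and DMSO libraries correlated above 0.1 in every pair in WT at 0 h (r 0.16 to 0.2) and in card1 at 0 h (0.2 to 0.33), 0.5 h (0.15 to 0.3) and 1 h (0.16 to 0.3). In those comparisons the replicate numbers were taken to pair the libraries. The main fit held no replicate block, so its counts leave out this pairing there too, and the fit with a block is an alternative.

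The procedure was tested on simulated counts with 200 genes changed by known folds among 19737 genes. The changed genes were drawn from those with a mean log2 CPM of at least 1, and card1 was given no response. Counts were drawn independently per gene and library, with no shared replicate effect. In the simulated WT comparison at 0.5 h it recovered 86.5% of them with 8 false calls (62, 86, 100 and 98% at folds of 1.5, 2, 3 and 4). For the difference of responses at 0.5 h it recovered 68% (30, 58, 92 and 92% at the same folds). With a simulated length trend, 2284 unchanged genes were called without the length correction and 9 with it.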

Results

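Whole seedlings of Arabidopsis thaliana were profiled by mRNA sequencing to compare the response to the quinone DMBQ in WT and in card1, a mutant of the receptor kinase gene CARD1. DMBQ is a benzoquinone related to breakdown products of lignin and is known as an inducer of haustoria in parasitic plants. Each of the 16 groups (WT or card1, DMBQ or DMSO, 0, 0.5, 1 or 6 h) held 3 libraries of 4764682 to 14492051 gene counts. The first 2 principal components of log2 CPM held 32.8% and 11.6% of the variance between the 48 libraries.

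CARD1 (AT5G49760, chromosome 5, positions 20216332 to 20221382 of TAIR10.1) was lower in card1 than in WT in every group compared. In DMSO its level in WT was 89.7 ± 4.2 CPM at 0 h, 90.4 ± 4.8 at 0.5 h, 71.2 ± 3.9 at 1 h and 88.7 ± 10 at 6 h (SD, n = 3 each). The card1 libraries held 30.3 ± 1.1, 27.8 ± 2.3, 19.9 ± 3.3 and 31.2 ± 3.6 CPM. With DMBQ the means were 93.5 ± 3.3, 81.8 ± 5.9, 74.8 ± 5.4 and 83 ± 8.5 CPM in WT and 29.9 ± 0.41, 30.4 ± 1.7, 22.2 ± 0.61 and 31.3 ± 1.7 CPM in card1. WT exceeded card1 by 2.66 to 3.6-fold, and in all 8 comparisons CARD1 was the gene with the smallest p. Transcript of the mutated gene was thus still counted in card1 at a reduced level.

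**Figure D1:**
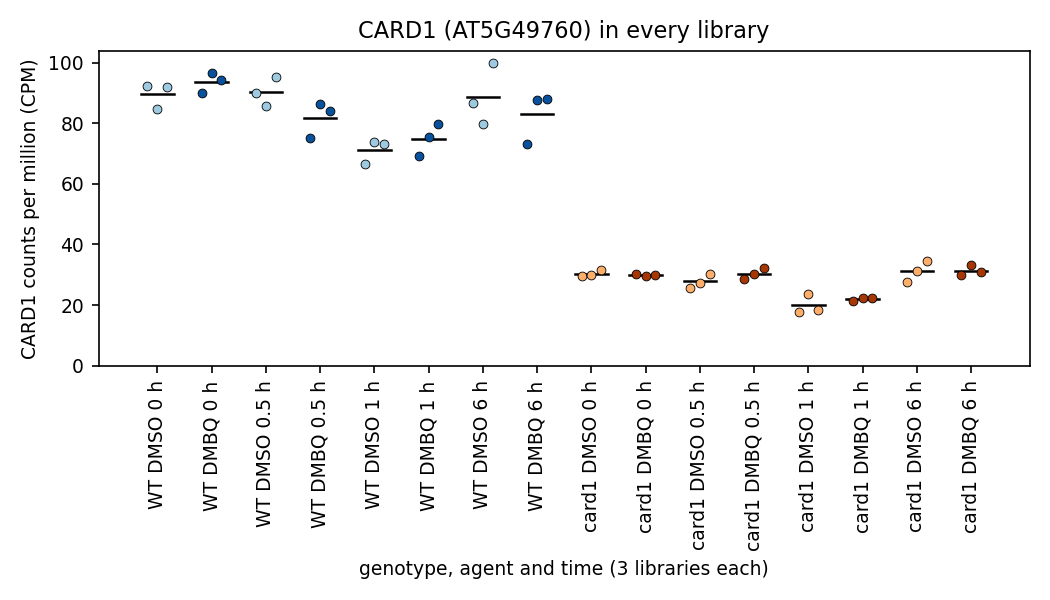
CARD1 level in CPM (y axis) in each of the 48 libraries, by genotype, agent and time (x axis), with points for libraries and a line at the mean of 3 libraries. The card1 means lie between 19.9 and 31.3 CPM and the WT means between 71.2 and 93.5 CPM.

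After 0.5 h of DMBQ, a pair of cupin-domain genes led the rise in WT. AT1G50590 rose 50.7-fold (log2 fold change 5.66 ± 0.33 SE, n = 3 against 3, adjusted p 1.94e-23) and AT2G43120 rose from 9.65 ± 1.1 to 245 ± 26 CPM (4.69 ± 0.18). GT72B1, a glucosyltransferase that conjugates phenols and xenobiotics, rose from 32.5 ± 4.2 to 185 ± 21 CPM (2.51 ± 0.17, adjusted p 6.02e-13). The stress transcription factors WRKY51 (2.67 ± 0.43), ZAT11 (2.56 ± 0.42) and DREB2A (2.31 ± 0.26) and the glutathione S-transferase GSTU25 (2.17 ± 0.33) also rose. Among falling genes were the cytochrome P450 gene CYP718 (−1.86 ± 0.37, adjusted p 0.00205) and the root hair specific gene RHS12 (−1.62 ± 0.26, adjusted p 6.23e-05). In all, 292 genes rose and 194 fell relative to DMSO at the same time, which is what rose and fell mean in each treatment comparison.

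By list at 0.5 h in WT, 15 of 23 lists passed camera, 13 upward. Of 22 xenobiotic conjugation and oxidation genes 5 rose (6 adjusted over the list alone), with UGT73B5 at 1.53 ± 0.23 and UGT73B3 at 1.68 ± 0.31 (camera adjusted p 8.96e-09, adjusted p = 0.101 with an estimated correlation). Of 29 jasmonic acid genes 6 rose (9 adjusted over the list alone), among them the biosynthesis genes AOS (0.6 ± 0.15) and OPR3 (0.8 ± 0.2) and the repressor gene JAZ3 (0.52 ± 0.13). Their camera adjusted p was 2.79e-07 (adjusted p = 0.176 with an estimated correlation). Of 14 salicylic acid genes 4 rose (7 adjusted over the list alone), including the glutaredoxin gene GRXS13 (0.88 ± 0.18) and EDS16 (0.55 ± 0.15), which encodes isochorismate synthase. Of 12 tryptophan and camalexin synthesis genes 2 rose (6 adjusted over the list alone), IGMT2 (1.9 ± 0.38) and CYP79B2 (0.85 ± 0.21). Both of these lists held their call with an estimated correlation (adjusted p 0.0499 each), and no other list at 0.5 h did.

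Of 32 glutathione S-transferases 3 rose (7 adjusted over the list alone; camera adjusted p 4.13e-06, adjusted p = 0.144 with an estimated correlation), and of 23 WRKY factors 5 (6; 4.46e-05 and adjusted p = 0.206 with an estimated correlation). Early stress ERF, CBF and ZAT factors had 5 of 26 higher (6 adjusted over the list alone), with CEJ1 at 1.84 ± 0.29 (camera 6.56e-06, adjusted p = 0.234 with an estimated correlation). Redox and antioxidant enzymes had 3 of 17 higher (5 adjusted over the list alone), with MDHAR at 1.22 ± 0.28 and DHAR2 at 0.64 ± 0.16 (camera 6.09e-05, adjusted p = 0.0677 with an estimated correlation). Calcium signalling (2 of 31 higher, camera 0.000219), pattern-triggered immunity (2 of 26, 0.00143) and phenylpropanoid and lignin synthesis (1 of 13, 0.0043) had adjusted p = 0.234 with an estimated correlation. The pattern-triggered immunity genes that rose were the danger peptide gene PROPEP1 (1.38 ± 0.31) and the receptor gene PEPR2 (1.41 ± 0.28). Quinone, enone and carbonyl reductases (none of 13 called, camera 0.022, adjusted p = 0.234 with an estimated correlation) and photosynthesis (none of 14, 0.0125, adjusted p = 0.46 with an estimated correlation) passed upward. Ethylene (2 of 11 lower, ETR2 at −0.49 ± 0.12 and EBF2 at −0.44 ± 0.13; camera 0.0332, adjusted p = 0.206 with an estimated correlation) and root markers (1 of 16 lower, EXPA7 at −0.83 ± 0.19; 0.0349, adjusted p = 0.396 with an estimated correlation) passed downward. The calls of 4 lists were lost without 1 replicate number: quinone reductases (0.198 without replicate 1), ethylene (0.11 without replicate 1, 0.135 without replicate 3), photosynthesis (0.131 without replicate 2, 0.18 without replicate 3) and root markers (0.907 without replicate 2).

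The WT DMBQ libraries at 0.5 h stood apart in their trend with transcript length: relative expression correlated with length at −0.43 to −0.46 (Spearman, across genes, which are not independent replicates) against −0.17 to −0.23 in their DMSO controls. The fold change correlated with length at −0.4. With a per-library correction for length and GC content 313 genes were called, 271 of them shared with the 486, and the quinone reductase (camera adjusted p 0.0542), ethylene (0.0883) and photosynthesis (0.0978) lists no longer passed. Without DMSO replicate 1 the count was 197, without DMSO replicate 2 126, without DMBQ replicate 1 221 and without DMBQ replicate 3 196.

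**Figure D2:**
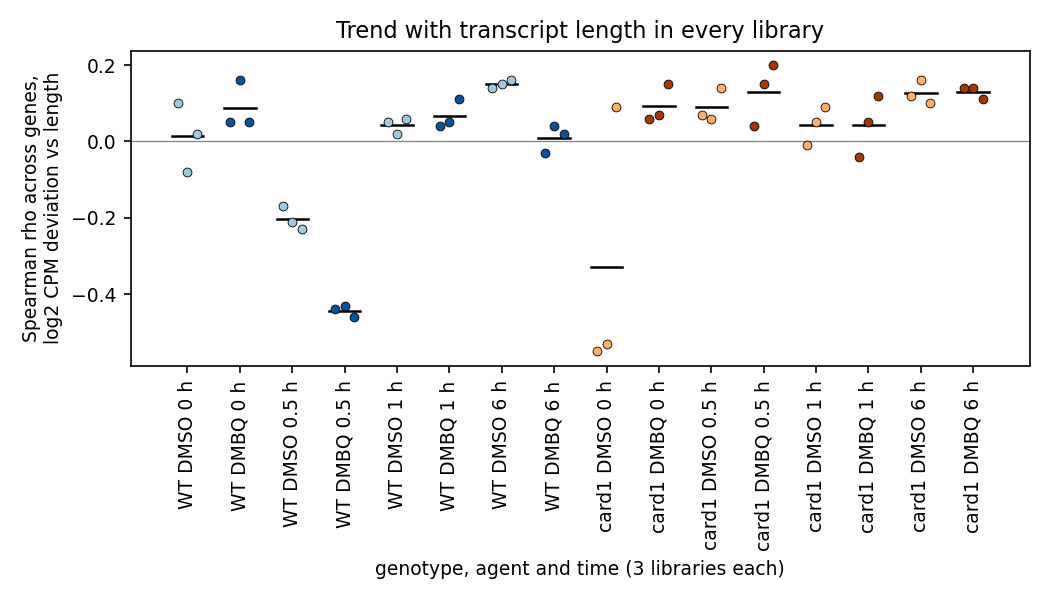
Spearman correlation, across genes with a mean log2 CPM of at least 1, of each library's expression relative to the mean of all libraries with transcript length (y axis), by genotype, agent and time (x axis), 1 point per library and a line at each group's mean. The 3 WT DMBQ libraries at 0.5 h (−0.43 to −0.46) and card1 DMSO replicates 1 and 2 at 0 h (−0.55 and −0.53) lie lowest.

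At 1 h in WT the same cupin genes reached 171-fold (AT1G50590, 7.42 ± 0.32, adjusted p 7.84e-30) and 85.5-fold (AT2G43120, 771 ± 32 against 8.95 ± 1.8 CPM; n = 3 against 3). ZAT11 (4.31 ± 0.47), GT72B1 (4.19 ± 0.17), WRKY51 (3.56 ± 0.35), the glucosyltransferase gene UGT73B4 (3.51 ± 0.44) and GSTU25 (3.1 ± 0.27) rose. The cytochrome P450 gene CYP81D11 was higher with DMBQ than with DMSO (4.04 ± 0.75). Its means at 0, 0.5 and 1 h were 35.4, 9.1 and 27.2 CPM with DMBQ and 44.1, 3.4 and 1.62 CPM with DMSO, so it lay below its 0 h level in both. The xyloglucan-modifying genes XTH13 (−2.47 ± 0.56) and XTH26 (−2.13 ± 0.41) and the arabinogalactan protein gene FLA6 (−2.24 ± 0.45) fell. The ERF transcription factor gene RAP2.11 fell by 2.35 on the log2 scale (SE 0.4, adjusted p 1.22e-05). In all, 412 genes rose and 139 fell. Of the 292 risers at 0.5 h, 121 also rose at 1 h, where independent lists of these sizes would share 6.1.

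By list at 1 h in WT, 12 passed, 11 of them upward. Of 22 xenobiotic genes 12 rose (14 adjusted over the list alone), with UGT73B5 at 2.4 ± 0.21 and UGT73B3 at 2.99 ± 0.28 (camera adjusted p 4.77e-42, and 8.73e-05 with an estimated correlation). Salicylic acid genes (5 of 14 higher, 6 adjusted over the list alone), led by GRXS13 (2.16 ± 0.16) and the salicylate receptor gene NPR4 (1.16 ± 0.14), and WRKY factors (6 of 23, 9 adjusted over the list alone), with WRKY75 at 2.19 ± 0.29, also held with an estimated correlation (0.00092 and 0.0155). Glutathione S-transferases had 7 of 32 higher (10 higher and 1 lower adjusted over the list alone), with GSTU22 at 2.66 ± 0.31 (camera 5.95e-09, adjusted p = 0.0505 with an estimated correlation). Early stress ERF, CBF and ZAT factors had 6 of 26 higher, with DREB2A at 2.88 ± 0.24 (1.16e-12, adjusted p = 0.0514 with an estimated correlation). Quinone, enone and carbonyl reductases had 3 of 13 higher: FQR1, a quinone reductase gene (1.16 ± 0.13), OPR1 (2.6 ± 0.38) and OPR2 (1.27 ± 0.3). The camera adjusted p was 0.000511 for that list, 0.00177 for redox enzymes (2 of 17 higher, DHAR2 at 1.23 ± 0.14) and 4.86e-05 for phenylpropanoid genes (2 of 13 higher, CAD5 at 1.35 ± 0.16 and PAL1 at 1.14 ± 0.16). Each of the 3 had adjusted p = 0.101 with an estimated correlation.

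Calcium signalling genes passed with 3 of 31 higher and the calmodulin gene CAM8 lower (−1.36 ± 0.36; camera 1.54e-06, adjusted p = 0.117 with an estimated correlation). Pattern-triggered immunity passed with 2 of 26 higher (9.86e-05, adjusted p = 0.144 with an estimated correlation). Jasmonic acid passed with none of 29 called (0.0333, adjusted p = 0.561 with an estimated correlation), and its p was 0.636 without replicate 1. Root markers passed downward with EXPA7, a root hair expansin gene, at −1.06 ± 0.19 (0.000195, adjusted p = 0.123 with an estimated correlation). The other lists did not pass: abscisic acid (0.0726, ABF3 higher at 0.83 ± 0.1), LRR VIII-1 receptor kinases (0.202), tryptophan and camalexin (0.296), mitochondrial retrograde response (0.326), ethylene (0.376), photosynthesis (0.426), xyloglucan endotransglucosylases (0.457), circadian clock (0.659), heat shock (0.723, HSF A4A higher than in DMSO at 1.01 ± 0.17), auxin and iron homeostasis (0.906 each).

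**Figure D3:**
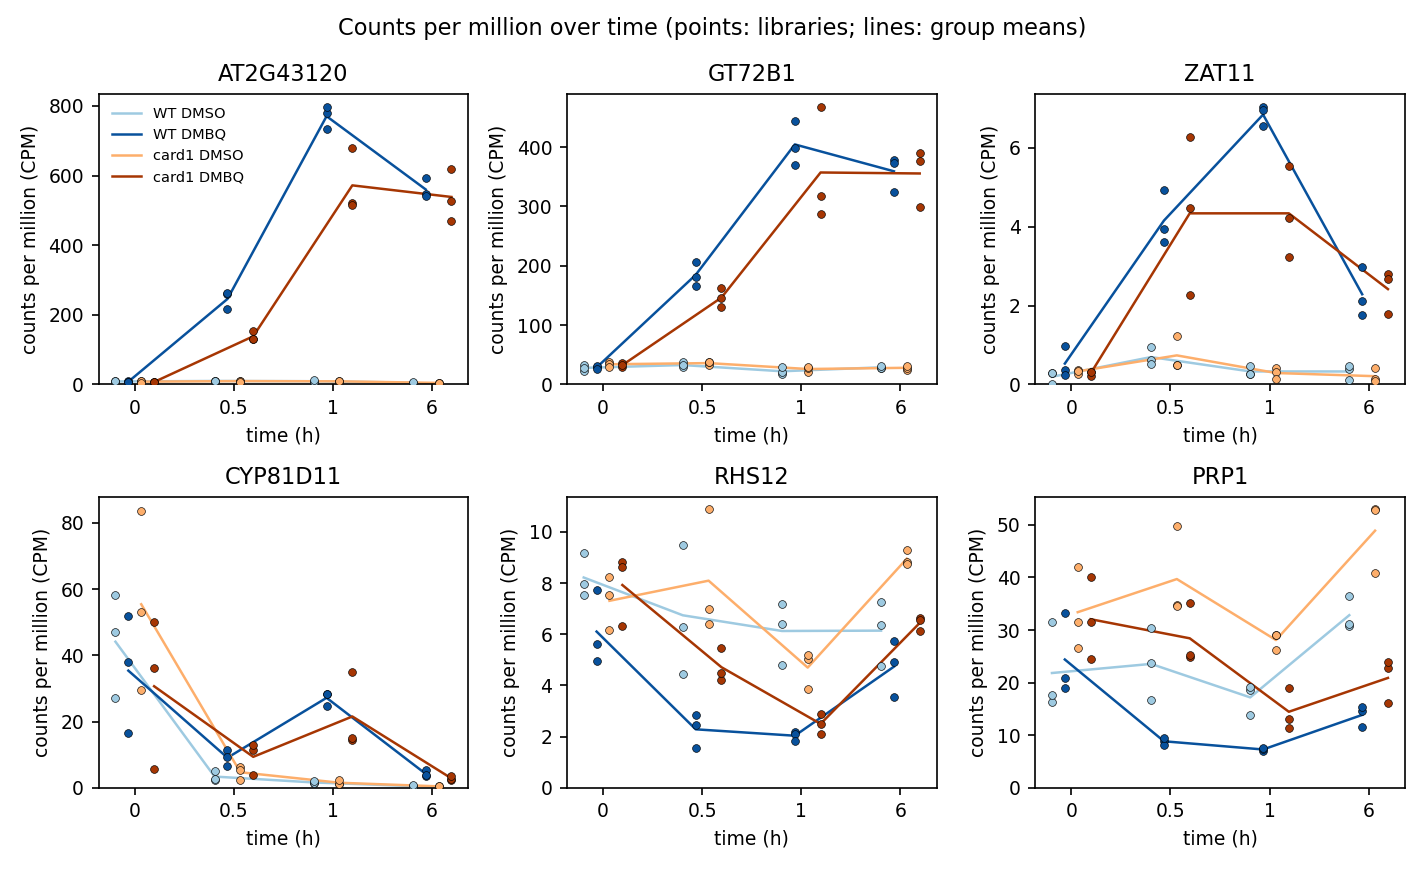
Levels in CPM (y axes, from 0) of AT2G43120, GT72B1, ZAT11, CYP81D11, RHS12 and PRP1 at 0, 0.5, 1 and 6 h (x axis), with points for libraries and lines through the means of 3 libraries for WT and card1 with DMBQ and DMSO. AT2G43120 reached 771 CPM in WT and 572 CPM in card1 at 1 h with DMBQ, and RHS12 lay at 2.04 and 2.5 CPM against 6.13 and 4.7 CPM in DMSO.

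At 6 h in WT AT1G50590 (160-fold) and AT2G43120 (116-fold, 560 ± 28 against 4.81 ± 0.55 CPM, n = 3 against 3) stayed highest, with GT72B1 at 3.65 ± 0.17. The oxophytodienoate reductase gene OPR1 was higher with DMBQ (2.9 ± 0.56, adjusted p 0.00108, 55 against 7.53 CPM), though below its 0 h levels of 213 CPM with DMBQ and 220 in DMSO. The xylem NAC factor gene XND1 (2.86 ± 0.56), the nitrilase gene NIT2 (2.62 ± 0.54) and the peroxidase gene PER4 (3.16 ± 0.72) rose. The lectin gene AT1G52050 fell by 1.25 on the log2 scale (SE 0.2, adjusted p 0.000122). In all, 202 genes rose and 41 fell, and 100 of the 412 risers of 1 h rose again, where independent lists would share 4.2.

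Phenylpropanoid and lignin synthesis was the list with the smallest p at 6 h in WT. Of 13 members 9 rose (11 adjusted over the list alone), with CAD5, a monolignol dehydrogenase gene, at 2.28 ± 0.17, the entry enzyme gene PAL1 at 1.7 ± 0.17, 4CL1 at 0.85 ± 0.12 and HCT at 0.71 ± 0.11 (camera adjusted p 9.7e-37, and 4.48e-06 with an estimated correlation). The list passed downward from 0 to 6 h in DMSO (7.46e-05, adjusted p = 0.142 with an estimated correlation), and among its risers PAL2 (111 CPM) and AT1G15950 (75.5 CPM) stayed below their 0 h levels (134 and 98.2 CPM in the DMBQ group). Quinone, enone and carbonyl reductases (2 of 13 higher, FQR1 at 1.31 ± 0.14), xenobiotic genes (3 of 22, 7 adjusted over the list alone) and glutathione S-transferases (5 of 32, 8 adjusted over the list alone, GSTU8 at 2.06 ± 0.29) also held with an estimated correlation (0.0162, 0.0169 and 0.019). Redox enzymes (1 of 17 higher; camera 0.00035, adjusted p = 0.0683 with an estimated correlation), WRKY factors (1 of 23; 0.000376, adjusted p = 0.371 with an estimated correlation) and ERF, CBF and ZAT factors (2 of 26; 0.00011, adjusted p = 0.443 with an estimated correlation) passed at the preset correlation. So did pattern-triggered immunity (1 of 26, 0.00956) and tryptophan and camalexin synthesis (none of 12, 0.0481), each with adjusted p = 0.446 with an estimated correlation. These last lists lost their calls without replicate 2 (0.0784 and 0.153) and without replicate 3 (0.0563 and 0.216), and with the length correction the tryptophan list had 0.058. The count of 243 genes was 134 without DMSO replicate 2 and 159 without DMSO replicate 3, and 764 (494 higher) when only the compared libraries were fitted.

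In card1 at 0.5 h 27 genes rose and 3 fell. AT1G50590 rose 30.9-fold (4.95 ± 0.37), AT2G43120 rose from 9.26 ± 1.6 to 138 ± 13 CPM (3.89 ± 0.19), and ZAT11 (2.61 ± 0.45), DREB2A (2.2 ± 0.31) and GT72B1 (2.03 ± 0.17, adjusted p 4e-10) rose (n = 3 against 3). AT4G10420, annotated with FBD and leucine-rich repeat domains, fell by 1.69 on the log2 scale (SE 0.32, adjusted p 0.0018). At the preset correlation 10 lists passed, none with an estimated one. ERF, CBF and ZAT factors had 2 of 26 higher and 10 adjusted over the list alone (camera adjusted p 1.34e-14, adjusted p = 0.144 with an estimated correlation). Xenobiotic genes had 1 of 22 (5 adjusted over the list alone; 4.98e-08) and WRKY factors 1 of 23 (8 adjusted over the list alone; 7.56e-07), both with adjusted p = 0.192 with an estimated correlation. The remaining 7, with the camera adjusted p and then the adjusted p with an estimated correlation, were heat shock (0.00191, 0.242), salicylic acid (0.00745, 0.242), jasmonic acid (0.00472, 0.483), pattern-triggered immunity (0.0143, 0.483), iron homeostasis downward (0.0457, 0.483), photosynthesis (0.0319, 0.624) and calcium (0.0462, 0.624). With RLE factors calcium had 0.0558, and with the length and GC correction 0.0523. Each of these 7 lost its call without at least 1 replicate number: iron (0.272) and photosynthesis (0.576) without replicate 1, iron (0.214), heat shock and salicylic acid (0.0558 each) without replicate 2, and calcium (0.698), immunity (0.408), jasmonic acid (0.211) and salicylic acid (0.0854) without replicate 3. The gene count was 18 without DMSO replicate 1, 17 without DMSO replicate 2, 16 without DMBQ replicate 3 and 10 with only the compared libraries.

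At 1 h in card1 194 genes rose and 41 fell, with AT1G50590 at 133-fold, AT2G43120 at 65.5-fold (572 ± 93 against 8.67 ± 1.9 CPM), WRKY51 at 4.37 ± 0.71, ZAT11 at 3.88 ± 0.63 and GT72B1 at 3.78 ± 0.17 (n = 3 against 3). WRKY51 and ZAT11 lay at 0.233 and 0.288 CPM in DMSO, so their fold changes rest on few reads. With DMBQ WRKY51 stood at 5.22 CPM in card1 and 9.35 CPM in WT at 1 h. RAP2.11 (−2.19 ± 0.44), FLA6 (−1.89 ± 0.41) and CYP702A5 (−1.46 ± 0.3) fell. Xenobiotic genes (8 of 22 higher, 14 adjusted over the list alone, UGT73B5 at 2.27 ± 0.24), salicylic acid (3 of 14, 4 adjusted over the list alone, GRXS13 at 1.91 ± 0.18) and quinone reductases (3 of 13, FQR1 at 0.96 ± 0.14 and OPR1 at 2.14 ± 0.39) rose as lists and held with an estimated correlation (0.000312, 0.0121 and 0.036). Glutathione S-transferases (5 of 32 higher, GSTU25 at 2.47 ± 0.31; camera adjusted p 7.83e-08) and ERF, CBF and ZAT factors (7 of 26, DREB2A at 3.09 ± 0.31; 2.41e-11) had adjusted p = 0.0714 with an estimated correlation. WRKY factors (4 of 23; 9.57e-07, adjusted p = 0.106 with an estimated correlation) and phenylpropanoid genes (2 of 13; 7.52e-05, adjusted p = 0.125 with an estimated correlation) also passed. Pattern-triggered immunity upward and root markers downward (0.0205 each, adjusted p = 0.454 with an estimated correlation) lost their calls without replicate 3 (0.179) and replicate 1 (0.388) respectively. With only the compared libraries 153 genes were called.

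At 6 h in card1 165 genes rose and 44 fell. AT2G43120 stood 131-fold and AT1G50590 95-fold above DMSO, and GT72B1 (3.67 ± 0.17), ZAT11 (3.57 ± 0.69) and PER4 (3.2 ± 0.62) rose (n = 3 against 3). LRL3, a root hair bHLH factor gene, fell by 1.33 on the log2 scale (SE 0.28, adjusted p 0.00354) and the proline-rich protein gene PRP1 by 1.23 (SE 0.23, adjusted p 0.00153). Phenylpropanoid genes again had the smallest list p (9 of 13 higher, 10 adjusted over the list alone, CAD5 at 2.24 ± 0.16 and PAL4 at 1.37 ± 0.16; camera adjusted p 1.26e-47, and 3.43e-07 with an estimated correlation), of which PAL2, ATCAD4 and CCoAOMT1 lay below the mean of their 2 groups at 0 h. Quinone reductases held as well (2 of 13 higher; 0.0286 with an estimated correlation), with OPR1 at 2.72 ± 0.49 but, at 60.2 CPM, below its 0 h levels of 173 CPM with DMBQ and 289 in DMSO. Xenobiotic genes (2 of 22 higher; 8.71e-11, adjusted p = 0.0755 with an estimated correlation), glutathione S-transferases (3 of 32, GSTU22 at 2.38 ± 0.47; 8.71e-06, adjusted p = 0.197 with an estimated correlation), ERF, CBF and ZAT factors (2 of 26; 0.00302, adjusted p = 0.646 with an estimated correlation) and, downward, auxin (none of 11; 0.012, adjusted p = 0.218 with an estimated correlation, 0.0635 without replicate 3) passed at the preset correlation. The count of 209 genes was 134 without DMSO replicate 1 and 132 without DMBQ replicate 3.

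**Figure D4:**
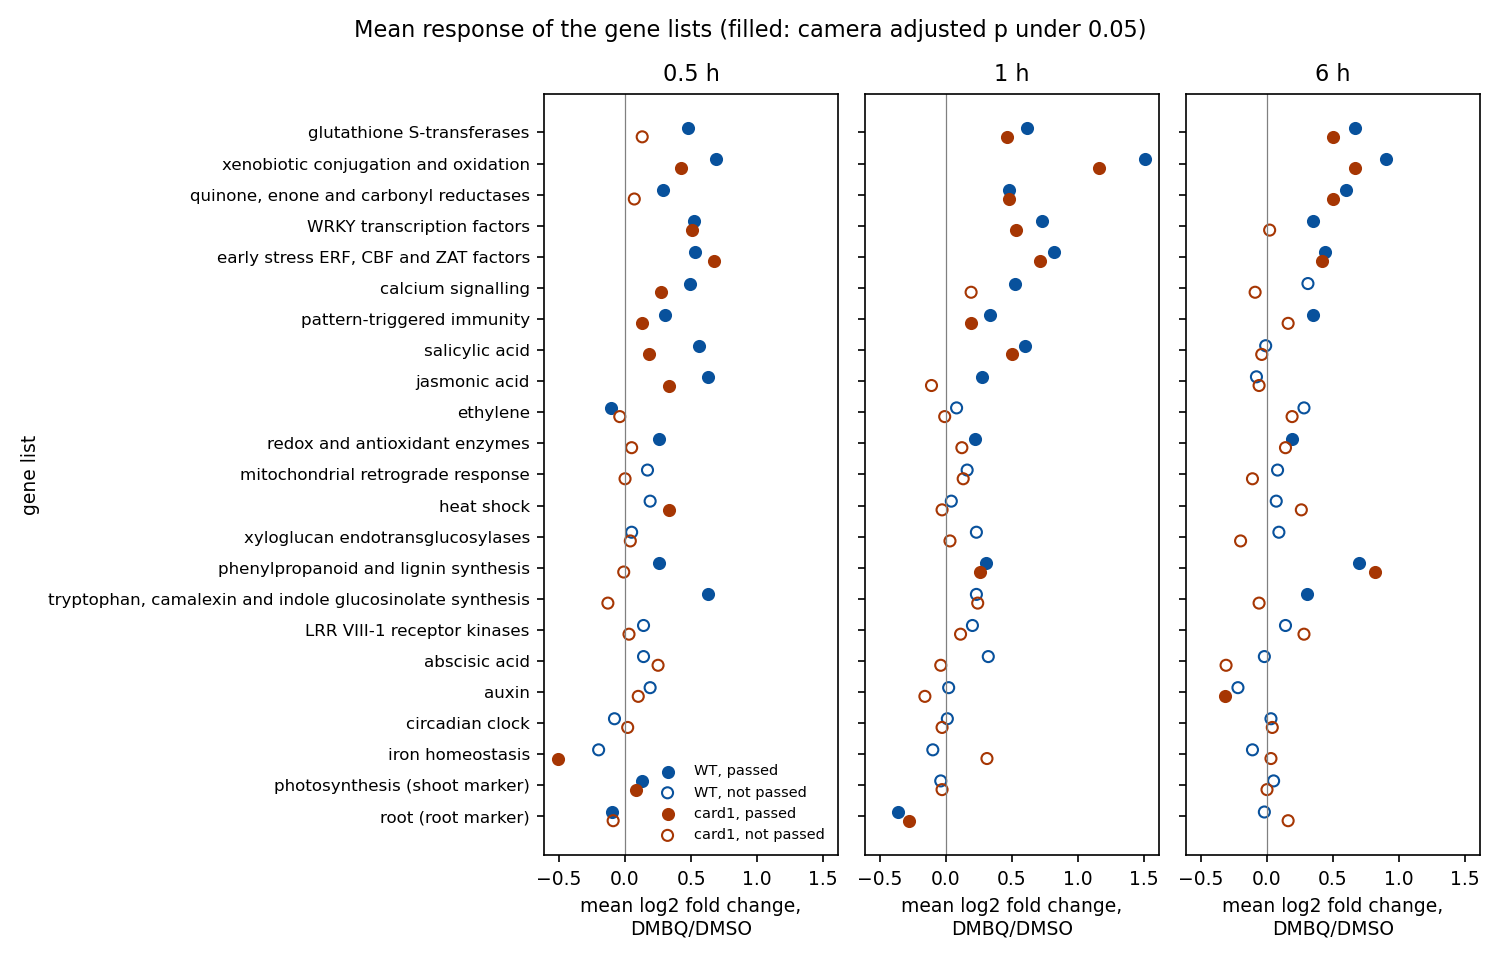
Mean log2 fold change of DMBQ against DMSO (x axis) of the tested members of each of the 23 gene lists (y axis) at 0.5, 1 and 6 h, in WT (blue) and card1 (red), with filled points where camera's adjusted p at the preset correlation was under 0.05. At 1 h 12 lists passed in WT and 9 in card1.

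The difference of the 2 genotypes' responses was tested directly. At 0.5, 1 and 6 h edgeR called 0 genes (2009, 460 and 1041 at an unadjusted p under 0.05), while DESeq2 called 9, 1 and 0. The joint test over these times also called 0 (1189 at an unadjusted p under 0.05, smallest adjusted p 0.106), and DESeq2 called 3. At 0.5 h the smallest adjusted p was 0.117, 63 genes were called without card1 DMSO replicate 3 and 1 each without WT DMSO replicate 2 or 3, and 5 with only the compared libraries. In simulated data this test recovered 58% of genes whose responses differed 2-fold at 0.5 h, so smaller differences were often not detectable with these libraries. The simulation changed only genes with a mean log2 CPM of at least 1, so recovery among lower ones is not known. The joint tests of DMBQ against DMSO called 1045 genes in WT and 375 in card1, and 2043 in WT with only the compared libraries. Of the WT calls at 0.5, 1 and 6 h, 163, 275 and 108 had an absolute log2 fold change of at least 1, as did 26, 154 and 84 of those in card1.

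Genes that rose in WT had the same sign in card1 for 72.6% of 292 at 0.5 h, 97.8% of 412 at 1 h and 97.5% of 202 at 6 h. Shared risers numbered 22, 178 and 122, where independent lists would share 0.4, 4 and 1.7. The median log2 fold change of the 1 h risers was 1.07 in WT, where they were selected, and 0.73 in card1. Scored at a time when they were not selected, the 1 h risers stood at 0.634 ± 0.074 (SD, n = 3) in WT and 0.436 ± 0.13 in card1 at 0.5 h (exact permutation p 0.2), and the 1 h fallers at −0.607 ± 0.12 and −0.304 ± 0.099 (exact permutation p 0.1, the smallest 3 against 3 libraries allow). At 1 h the 6 h risers stood at 0.926 ± 0.038 in WT and 0.727 ± 0.1 in card1 (exact permutation p 0.1). At 6 h the 1 h risers stood at 0.661 ± 0.059 and 0.591 ± 0.098 (exact permutation p 0.4). Over all 12 such sets the card1 value was nearer to 0 in 11. The exception was the 1 h fallers at 6 h (−0.252 ± 0.097 in WT and −0.259 ± 0.058 in card1, exact permutation p 0.9), and with the length and GC correction the 0.5 h fallers at 6 h (−0.19 and −0.199). No p could reach 0.05 in this design, and the sets share genes and libraries. All 12 sets were chosen by calls in WT, which can favour genes that respond more in WT. A lower card1 value can thus arise in part from the choice of genes. The SDs and p-values took each DMSO mean as fixed, so they leave out its error, and scores were not taken within replicate pairs. For 1 h fallers at 0.5 h, the difference of 0.303 between card1 and WT was 0.234 without WT DMSO replicate 2.

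**Figure D5:**
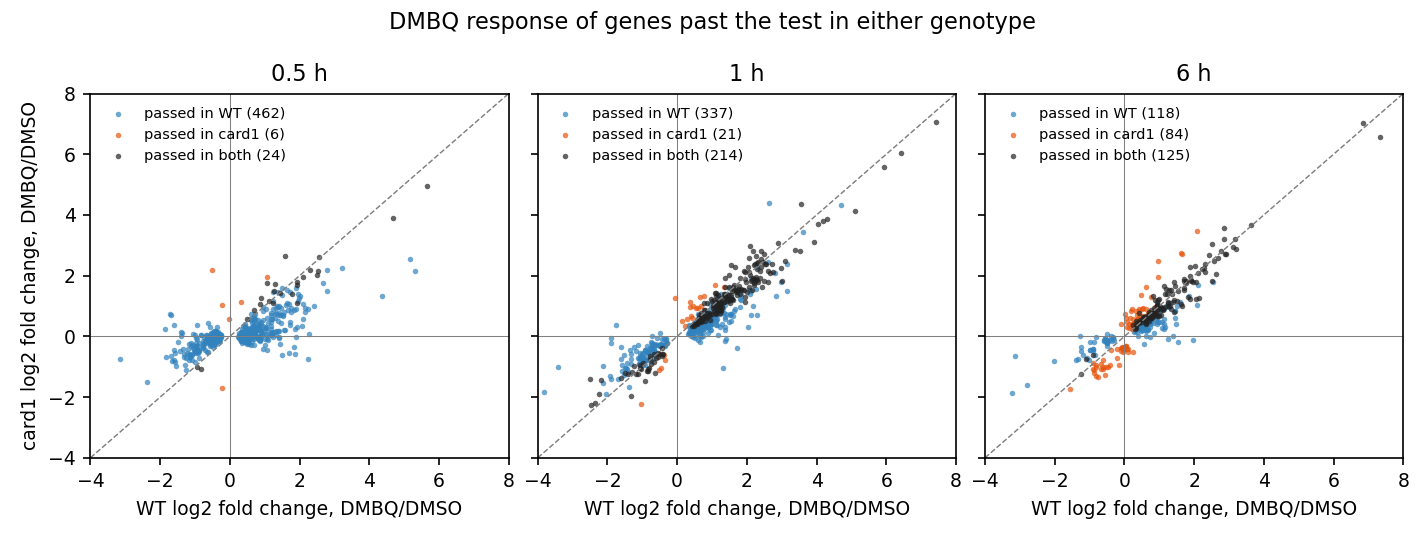
Log2 fold change of DMBQ against DMSO in card1 (y axis) against WT (x axis) at 0.5, 1 and 6 h. Points are genes that passed in WT, in card1 or in both, coloured accordingly. Genes that passed in neither are not drawn. The 412 genes that rose in WT at 1 h had a median of 1.07 in WT and 0.73 in card1.

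At 0 h, where no response time had passed, 25 genes were higher in WT DMBQ than in WT DMSO libraries, all of the organelle genomes, with ATCG00510 at 10.7 ± 1.9 against 2.21 ± 0.52 CPM (2.34 ± 0.41, adjusted p 0.00371, n = 3 against 3). Leaving out WT DMSO replicate 2 or 3 left 0 of these calls, and leaving out DMBQ replicate 1, 2 or 3 left 9, 9 and 2, while 46 genes were called in a paired fit with a replicate block and 46 with only the compared libraries. DESeq2 called 53. The WRKY list passed with none of 23 called (0.0228, adjusted p = 0.992 with an estimated correlation, 0.378 without replicate 1 and 0.234 without replicate 3). In card1 at 0 h 721 genes were higher with DMBQ, among them the ankyrin repeat gene AT5G54720 (1.67 ± 0.45), and 361 lower, including the peroxiredoxin gene TPX1 (−0.39 ± 0.078). Redox enzymes (3 of 17 lower, 7 adjusted over the list alone; camera adjusted p 0.000699, adjusted p = 0.227 with an estimated correlation) and quinone reductases (2 of 13 lower; 0.00103, adjusted p = 0.232 with an estimated correlation) passed downward. So did glutathione S-transferases (1 of 32; 0.0162), and pattern-triggered immunity passed upward (1 of 26; 0.0221), both with adjusted p = 0.993 with an estimated correlation. The glutathione S-transferase call was lost without replicate 1 (0.287) or 2 (0.0692), and that of immunity without replicate 1 (0.13) or 3 (0.134).

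These card1 calls moved with transcript length: the fold change correlated with length at 0.59 across genes, genes called higher had a median length of 4079 bases and genes called lower one of 980.5, against 1754 for all tested. Expression relative to the mean of all libraries correlated with length at −0.55 and −0.53 in card1 DMSO replicates 1 and 2. The count of 1082 was 6 with the length and GC correction, 7 without DMSO replicate 1, 0 without DMSO replicate 2, 4067 without DMSO replicate 3, and 385, 502 and 434 without DMBQ replicates 1, 2 and 3. Fitted with only the compared libraries it was 0 (4158 at an unadjusted p under 0.05 with all libraries, and 1543 by DESeq2, which gave 8077 genes no adjusted p). With the correction AT5G54720 had adjusted p 0.154 and the glutathione S-transferase list 0.232.

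In DMSO 2627 genes were higher and 2477 lower in card1 than in WT over the 4 times (n = 12 against 12). Genotype goes with the line and its growth here, so these counts cannot be assigned to CARD1 alone. Libraries of the same replicate number may share a batch, and the 12 libraries per genotype may then not be independent. CARD1 fell by 1.65 on the log2 scale (SE 0.047, adjusted p 3.79e-29). ACR5, a gene of the ACT domain repeat family, was higher at 62 ± 16 against 20.1 ± 3.1 CPM (1.61 ± 0.067), as were the glyoxylate cycle gene ICL (1.56 ± 0.28) and the NAC factor gene NAC044 (1.54 ± 0.14). FLC, a repressor of flowering, lay at 0.269 ± 0.25 against 3.72 ± 0.54 CPM (−3.96 ± 0.45, adjusted p 1.01e-13), and the RING finger gene LUL4 was lower (−1.98 ± 0.12). LRR VIII-1 receptor kinases, the family of CARD1, had 3 of 7 lower: CARD1 itself, its chromosomal neighbour AT5G49770 (−0.56 ± 0.13) and AT5G01950 (−0.2 ± 0.064), with camera adjusted p 3.3e-10 and 3.37e-05 with an estimated correlation. That pass rested on CARD1 itself: without it the other 6 had a camera adjusted p of 0.179, and 0.445 with an estimated correlation. The mitochondrial retrograde response had 5 of 8 higher (6 adjusted over the list alone), with the alternative dehydrogenase genes NDA1 (0.45 ± 0.079) and NDB2 (0.38 ± 0.087), and held with an estimated correlation (0.0263).

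Photosynthesis genes had 7 of 14 higher in card1, RBCS1A by 0.54 ± 0.049 (camera adjusted p 4.25e-05), and phenylpropanoid genes 6 of 13 higher and 1 lower, CCoAOMT1 at 0.49 ± 0.053 (0.00465), both with adjusted p = 0.445 with an estimated correlation. Redox enzymes had 7 of 17 higher and 2 lower (0.00465, adjusted p = 0.25 with an estimated correlation). The circadian clock list did not pass (0.877) with 4 of 19 higher and 6 lower, among them ELF4 (−0.61 ± 0.082) and TOC1 (−0.41 ± 0.063). Of the iron homeostasis genes 2 of 18 were higher and 6 lower (0.137), among the latter the ferric reductase gene FRO2 (−1.88 ± 0.56, adjusted p 0.00888, 0.0553 without WT DMSO 1 h replicate 2 and 0.0857 without WT DMSO 6 h replicate 2). Of the calls, 140 had an absolute log2 fold change of at least 1.

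Time in DMSO alone moved many genes in both directions (n = 6 against 6 libraries per time): 1899 rose and 1530 fell from 0 to 0.5 h, 3640 and 3569 at 1 h, and 4930 and 4991 at 6 h. At 0.5 h the disease resistance genes AT1G66090 (4.41 ± 0.57) and AT5G41750 (3.26 ± 0.36) rose. Of 31 calcium signalling genes 16 rose, the touch gene TCH2 by 1.48 ± 0.16 and CPK28 by 1.63 ± 0.15, and of 26 pattern-triggered immunity genes 14 rose and 1 fell, MPK3 by 1.25 ± 0.13. Xyloglucan endotransglucosylases had 6 of 8 higher, XTH18 by 2.3 ± 0.22, and ethylene genes 5 of 11, ACS11 by 2.42 ± 0.26. These lists held with an estimated correlation (0.0436, 0.0436, 0.00809 and 0.0436). CYP81D11 fell in DMSO from 49.8 ± 21 CPM at 0 h to 4.05 ± 1.8, 1.58 ± 0.43 and 0.487 ± 0.21 CPM at 0.5, 1 and 6 h. With only the compared libraries 2078 genes were called at 0.5 h, and without card1 DMSO 0 h replicates 1 and 2 the count at 1 h was 4556.

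At 1 h in DMSO the cold and drought gene LTI78 (2.48 ± 0.33) and the bHLH factor gene HEC1 (2.47 ± 0.27) rose, and the glucosyltransferase gene UGT73C1 fell by 3.06 on the log2 scale (SE 0.49). Phenylpropanoid genes (9 of 13 lower; camera adjusted p 2.87e-07, adjusted p = 0.142 with an estimated correlation) and xenobiotic genes (13 of 22 lower and 1 higher; 2.17e-06, adjusted p = 0.253 with an estimated correlation) passed downward in the DMSO controls. At 6 h the clock-linked genes JMJD5 (4.57 ± 0.14) and RVE2 (3.64 ± 0.15) and ELF4 (2.3 ± 0.11) rose, and PRR7 (−2.85 ± 0.13) and GI (−2.19 ± 0.11) fell. Photosynthesis genes had 13 of 14 lower, LHCB2.1 by −4.79 ± 0.22, xyloglucan endotransglucosylases 7 of 8 lower, TCH4 by −5.21 ± 0.43, and quinone reductases 11 of 13 lower and 2 higher, OPR1 by −4.94 ± 0.37. These lists held with an estimated correlation (0.00482, 0.0247 and 0.0251). All but 16 of the 412 genes higher with DMBQ than with DMSO at 1 h in WT, and all but 24 of the 202 at 6 h, had a mean with DMBQ above the mean of the WT DMSO and DMBQ groups at 0 h.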

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

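In this part the length and GC correction was chosen after the trend with transcript length was seen, and the splits of the samples after the counts were seen. Bounds for the depth and length tests were reworded after the results from numbers to shares of the counts, with the same values. The other tests were planned before their results.

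Responses of the 2 genotypes differed, by the test of the difference, for 2 genes at 0 h: ILA (0.78 ± 0.15, adjusted p 0.0397), a gene linked to immunity, and the organelle gene ATCG00300 (−1.9 ± 0.34, adjusted p 0.0397), both card1 minus WT. With the length and GC correction their adjusted p were 0.938 and 0.08. DESeq2 called 105 genes, 91 higher and 14 lower, but gave about 15000 genes no adjusted p, so it adjusted over fewer genes than edgeR. The count of 2 was 0 without any 1 of WT DMSO replicates 2 and 3, the 3 WT DMBQ replicates, card1 DMSO replicates 1 and 2 and card1 DMBQ replicate 3, 1 without card1 DMBQ replicate 1 or 2, 16 without WT DMSO replicate 1 and 1549 without card1 DMSO replicate 3. By list at 0 h the median difference was −0.32 for glutathione S-transferases (camera adjusted p 0.0295, adjusted p = 0.974 with an estimated correlation), −0.41 for quinone, enone and carbonyl reductases (0.0133, adjusted p = 0.649 with an estimated correlation) and −0.18 for redox enzymes (0.0295, adjusted p = 0.649 with an estimated correlation). All 3 lost their calls without replicate 1 (0.926, 0.604 and 0.604), and redox enzymes without replicate 2 (0.0636). With the length and GC correction the first and last of them had 0.342 and 0.166.

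After 0.5 h of DMBQ 5 lists had lower DMBQ minus DMSO differences in card1 than in WT at the preset correlation. The median difference was −0.43 for tryptophan and camalexin synthesis (camera adjusted p 1.06e-05, adjusted p = 0.153 with an estimated correlation), −0.31 for glutathione S-transferases (0.00787, adjusted p = 0.56 with an estimated correlation) and −0.25 for jasmonic acid (0.0201, adjusted p = 0.841 with an estimated correlation). It was −0.17 for redox enzymes (0.00823, adjusted p = 0.449 with an estimated correlation) and −0.17 for phenylpropanoid synthesis (0.0101, adjusted p = 0.56 with an estimated correlation). Glutathione S-transferases and redox enzymes differed by as much at 0 h (−0.32 and −0.18), where no response time had passed. Their values at 0.5 h thus cannot be read as a weaker response to DMBQ. Without replicate 1 the glutathione S-transferase (0.219), phenylpropanoid (0.219) and jasmonic acid (0.272) lists no longer passed, and with the length and GC correction the glutathione S-transferase (0.0625) and redox (0.0609) lists did not.

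At 1 h the lists were xenobiotic conjugation (median −0.31, camera adjusted p 0.00416), calcium signalling (−0.26, 0.00261) and jasmonic acid (−0.34, 0.000154), each with adjusted p = 0.713 with an estimated correlation, and WRKY factors (−0.26, 0.0303, adjusted p = 0.733 with an estimated correlation). None of these 4 passed without replicate 1 (0.184, 0.141, 0.393 and 0.613), and WRKY factors did not without replicate 2 (0.0648). At 6 h WRKY factors differed by −0.32 (0.0307, adjusted p = 0.849 with an estimated correlation, 0.257 without replicate 1, 0.0651 with the length and GC correction).

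Between the card1 libraries taken at 0 h, 1082 genes passed although no response time had gone by. A trend with transcript length fits these calls: the fold change correlated with length at 0.59, and the correction left 6 calls, with the median absolute log2 fold change of the same genes going from 0.388 to 0.148 and their median SE from 0.1 to 0.081, so that the calls ended because the changes shrank. Wild-type material in card1 DMSO replicates 1 and 2 stays open. Its share was 0.17 for both together (95% bootstrap interval 0.032 to 0.25, over 40 genes), 0.096 for replicate 1 and 0.16 for replicate 2. After the correction the share for both was 0.092 (95% bootstrap interval 0.0041 to 0.18). CARD1 itself, at 29.5 and 29.8 CPM, was no higher there than in replicate 3 (31.5). Only with the correction did CARD1 stand at 36.8 against 29.6 in the other card1 libraries at 0 h. A change of the kind seen over time in DMSO also stays open. Across the called genes r with the WT DMSO change from 0 h was −0.43 at 0.5 h, which met the bound set in advance. It was 0.03 at 1 h and 0.14 at 6 h. With the correction r at 0.5 h was −0.17, a check added after −0.43 was seen. The WT DMSO libraries at 0.5 h held a length trend too (−0.17 to −0.23), so the −0.43 is not separate from length. Of the 10 splits of these 6 libraries 3 called at least as many genes, and the highest, 2323 with DMSO 1, DMSO 2 and DMBQ 2 against the rest, points to a structure of the samples.

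At 0.5 h 486 genes passed in WT and 30 in card1, while the test of the difference called 0 (2009 at an unadjusted p under 0.05 with edgeR, and 9 by DESeq2). Lower depth in card1 is argued against, since WT libraries thinned to the card1 depths still gave 358 calls (337 to 378 over 8 thinnings), and so is the length trend as the whole cause, since 313 calls were left after the correction. A larger spread between card1 replicates was not settled by its test: the median SD of log2 CPM was 0.184 in card1 and 0.146 in WT. The ratio of 1.26 lay between the bounds set in advance. All 48 libraries shared 1 dispersion per gene in the fit, so this spread entered the errors of both genotypes and not those of card1 alone. A smaller response in card1 is the biological candidate and remains a hypothesis: 1 h risers reached 0.687 of the WT response at 0.5 h (0.709 with the length and GC correction, past the bound of 0.7), and not all card1 libraries lay below all WT libraries. The genes scored were chosen by calls in WT, which can favour genes that respond more in WT. The scores were not taken within replicate pairs, so the spread of the card1 values can hold an effect shared by libraries of 1 replicate number.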

How the results depend on the processing

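The length and GC correction, the fits without card1 DMSO 0 h replicates 1 and 2 or without organelle genes, the genotype mean over 0.5, 1 and 6 h, the family of CARD1 without CARD1 and the score over genes called in card1 were chosen after the data were seen. No named gene changed direction in the alternatives run for it, while the score difference of 6 h fallers at 0.5 h changed sign (0.0478 to −0.166) over genes with an absolute log2 fold change of at least 1. RLE factors and a filter at mean log2 CPM of 1 kept every count of genes within 1.5 times, and so did no filter except at 0 h. Of 145 named gene results, 134 of the 135 to which DESeq2 gave an adjusted p kept their call with it, 132 kept it with the length and GC correction and 102 whichever single library was left out. Of 117 list calls, 25 kept theirs with an estimated correlation, 77 with fry, 116 with RLE factors and 103 with the length and GC correction. Simulated responses that differed 1.5-fold at 0.5 h were recovered in 30% of cases, among genes with a mean log2 CPM of at least 1. Where no cause is given, the cause was not tested.

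DESeq2 called 53 genes in WT at 0 h, and 105, 9, 1 and 3 for the difference of responses at 0, 0.5 and 1 h and jointly. For the difference at 0 h it gave about 15000 genes no adjusted p. A minimum absolute log2 fold change of 1, which by construction calls fewer, gave 163, 275 and 108 in WT at 0.5, 1 and 6 h, 19, 154 and 84 in card1 at 0, 1 and 6 h, 1 for the difference at 0 h, 140 between genotypes and 386, 557 and 1196 for DMSO time. Without a filter the difference at 0 h called 0. Only the compared libraries gave 46 in WT at 0 h, 764 in WT at 6 h, 0, 10 and 153 in card1 at 0, 0.5 and 1 h, 1 and 5 for the difference at 0 and 0.5 h, 2043 jointly in WT, 2 for the joint difference and 2078 for DMSO at 0.5 h.

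In the fit with a replicate block, WT at 0 h gave 46 calls and the difference at 0 h 4; no named gene or list lost its call with the block, and in card1 at 0.5 h 11 lists passed in place of 10. Over all groups, those where the numbers paired the libraries included, 45 of 48 libraries correlated best with their own number (mean r 0.072 for the same number in different groups and −0.036 for different numbers), a hint from the data only. Where the numbers did not pair the libraries by the set bound, the block gave 725 in WT at 0.5 h, 700 at 1 h, 303 at 6 h and 290 in card1 at 6 h. The length and GC correction together with a replicate block gave 43 in WT at 0 h and 15 and 327 in card1 at 0 and 6 h.

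The length and GC correction alone gave 313 in WT at 0.5 h, 6 in card1 at 0 h and 0 for the difference at 0 h, and 7, 1 and 0 passing lists in card1 at 0 h and for the differences at 0 and 6 h. Without card1 DMSO 0 h replicates 1 and 2, card1 at 0 h called 0, the difference at 0 h 0 and DMSO at 1 h 4556; 1 library was then left in that group, assumed to vary like the other groups, so that the loss of libraries alone can end calls. Without organelle genes WT at 0 h and the difference at 0 h called 0.

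With an estimated correlation the passing lists numbered 0, 2, 3 and 4 in WT at 0, 0.5, 1 and 6 h (from 1, 15, 12 and 9), 0, 0, 3 and 2 in card1 (from 4, 10, 9 and 6), 0 at each time for the difference (from 3, 5, 4 and 1), 2 between genotypes (from 5) and 4, 0 and 5 for DMSO time (from 13, 7 and 13). With fry, which does not compare a list with other genes, they were 0, 9 and 5 in WT at 0, 0.5 and 6 h, 2 and 0 in card1 at 0 and 0.5 h, 0 at each time for the difference, 8 between genotypes, and 13 and 22 for DMSO at 1 and 6 h. Score differences, card1 minus WT, over genes with an absolute log2 fold change of at least 1 were 0.177 for 0.5 h fallers at 1 h (0.0553 over all), −0.166 for 6 h fallers at 0.5 h (0.0478), −0.309 for 6 h risers at 1 h (−0.199) and 0.163 for 6 h fallers at 1 h (0.0718). Over genes called in card1, 6 h fallers at 0.5 h gave 0.289. Without CARD1 its family no longer passed between genotypes (0.179).

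Leaving out 1 library at a time gave 0 to 24 calls in WT at 0 h, 126 to 393 at 0.5 h, 368 to 503 at 1 h and 134 to 194 at 6 h. In card1 it gave 0 to 4067, 16 to 35, 160 to 226 and 132 to 249, for the difference 0 to 1549 at 0 h (1549 without card1 DMSO replicate 3, 16 without WT DMSO replicate 1), 0 to 63 at 0.5 h and 0 to 1 jointly. Lists passing without 1 replicate number were 0 to 8 in WT at 0 h, 2 to 5 and 6 to 9 in card1 at 0 and 0.5 h, 0 to 3, 4 to 8, 0 to 8 and 1 to 3 for the differences at 0, 0.5, 1 and 6 h, and 5 to 11 for DMSO at 1 h. The score difference of 0.5 h fallers at 1 h ranged from 0.03 to 0.087.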

Other observations

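The tests on root hair and endodermis genes and all splits of the samples in this part were chosen after the results were seen. The linkage test was planned before its result.

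Genes that the annotation calls root hair specific were lower with DMBQ as a group in both genotypes. Over 15 tested members the median log2 fold change was −0.84, −0.83 and −0.42 at 0.5, 1 and 6 h in WT (camera p 0.00871, 0.00418 and 0.0221 with an estimated correlation) and −0.56, −0.71 and −0.47 in card1 (0.00382, 0.00768 and 0.0225). Called lower were 5, 5 and 0 of the 15 in WT and 0, 0 and 2 in card1 at 0.5, 1 and 6 h, and none was called higher. The 5 in WT at 1 h were RHS12, a pectin methylesterase gene (−1.58 ± 0.24), RHS8 (−1.06 ± 0.29), RHS19 (−0.96 ± 0.23), RHS16 (−0.95 ± 0.26) and RHS13 (−0.83 ± 0.23). The members ranged from −1.58 to 0.58 there. The difference between the genotypes' responses had p 0.563, 0.622 and 0.915 with an estimated correlation at 0.5, 1 and 6 h.

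The set was chosen after falls of its members were seen in the same data. None of its p-values for a fall, in either genotype and at any time, is thus independent support for an effect on root hair genes. A lower share of root in the treated seedlings would lower endodermis genes (8 tested) alike. Their medians were 0.13 in WT at 6 h and 0.03, −0.05 and −0.04 in card1 at 0.5, 1 and 6 h. They lay above the root hair medians by 0.55 and by 0.6, 0.66 and 0.43 (lowest 95% bootstrap bound 0.15). This argues against a lower share of root as the whole cause of the fall at 6 h in both genotypes. A smaller loss is not excluded, as the bootstrap resampled genes, which are not independent, within the same libraries. Single endodermis genes ranged from −0.58 to 0.5 in WT at 6 h and from −0.28 to 0.3 in card1. In card1 at 0.5 and 1 h a lower share of root stays open as a part of the fall. There planned organ lists moved at the preset correlation. Photosynthesis passed upward at 0.5 h and root markers downward at 1 h, and both lost their calls without replicate 1 and with an estimated correlation. In WT at 0.5 and 1 h a lower share of root also stays open as a part of the fall. The endodermis medians of −0.13 and −0.26 did not lie near 0, though above the root hair medians by 0.71 and 0.57 (95% bootstrap intervals 0.25 to 1.05 and 0.19 to 0.91). A hypothesis that DMBQ lowers root hair expression may be worth a test in roots sampled alone.

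Splits of the samples were counted with all 48 libraries refitted. Each treatment comparison has only 10 splits of its 6 libraries, too few for a share under 0.05. The real split alone gave as many calls (1 of 10) in WT at 0 h (25, highest other 13), 0.5 h (486, highest other 1), 1 h (551, highest other 0) and 6 h (243, highest other 0), and in card1 at 0.5 h (30, highest other 7), 1 h (235, highest other 1) and 6 h (209, highest other 8). Replicate numbers pair the libraries in WT at 0 h and in card1 at 0, 0.5 and 1 h, where the real split parts all 3 pairs, as do 3 of the others. The highest count among those 3 was 0 in WT at 0 h and 479, 1 and 0 in card1 at 0, 0.5 and 1 h. The remaining 6 leave pairs together, and among them were the splits with 13 calls in WT at 0 h and 2323 in card1 at 0 h.

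With labels of agent exchanged within genotype and time over 0.5, 1 and 6 h, 1 of 25 splits reached the real count in WT (1045, highest other 259) and in card1 (375, highest other 244). This argues against chance for both joint tests. The same holds for card1 against WT in DMSO (5104, highest other 153, 1 of 25) and for DMSO time at 0.5 h (3429, highest other 2350), 1 h (7209, highest other 1903) and 6 h (9921, highest other 6696), each 1 of 25. A share of 1 of 25 is the smallest these splits allow, and it was not adjusted over the results tested. In card1 the joint splits did not keep replicate pairs parted, as the real split does at 0.5 and 1 h. All these splits exchanged single libraries. If libraries of the same replicate number share a batch across groups, fewer splits are independent, and the share of 1 of 25 is too small. Splits cannot address a technical trend that goes with the agent, such as the length trend of the WT DMBQ libraries at 0.5 h. Nor can they address a difference in line, growth or batch that goes with genotype or time. For the difference of responses at 0 h chance cannot be excluded, since 10 of 25 splits gave at least the real 2 calls (highest other 374, which points to a structure of the samples). At 0.5, 1 and 6 h and jointly the real count was 0 with edgeR (2009, 460, 1041 and 1189 at an unadjusted p under 0.05, and 9, 1, 0 and 3 by DESeq2), which all 20 of 20 splits reach by definition, so they say nothing about chance there (highest other 130, 185, 96 and 2). The splits with 130, 185 and 96 calls point to a structure that includes the agent: the labels of WT were all kept at 0.5 h and all exchanged at 1 h, and those of card1 all exchanged at 6 h, so the response of 1 genotype stayed whole.

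Genes with an absolute log2 fold change of at least 1 between card1 and WT in DMSO numbered 8 of 731 tested within 2 Mb of CARD1 and 129 of 18982 elsewhere (odds ratio 1.62, Fisher's exact test, one-sided p 0.14).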
